A study of Rattus norvegicus with 6 samples.

How the data were processed

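RNA of rat pancreas was measured in 2 groups, control and acute pancreatitis (AP), with 3 deposited scans per group. Per the labels, total RNA was extracted with TRIzol from the pancreas of each animal, ribosomal RNA was removed with a commercial kit, and the RNA was amplified with random primers and labelled with the dye Cy3 (Arraystar kits). Per the file headers, the arrays were read by Agilent Feature Extraction 11.0.1.1 with a 1-colour expression protocol, and the design was annotated on the rat assembly rn4. The deposited scanner tables give each spot's signal as an intensity after background subtraction and spatial detrending, with no scaling between arrays, and also the median spot and background intensity. The deposited normalized table is in log2, with nearly the same distribution on all arrays and a floor value; the tool that made it is not given in the sources used here. Group and replicate of each scan were taken from the labels.

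The files showed that control 3 is a second scan of the array of control 2, and AP 3 of the array of AP 2. The test compared deviations of spots from the mean of their probe over 676 probes with a signal above 200, and pairs with r above 0.9 were taken as 1 array. The SD of the log2 difference between probe means was at most 0.0368 in these pairs and 0.244 to 0.337 in the other pairs of a group. The design fixed before the data were examined took the 6 scans as 6 arrays; the fit departed from it, averaged the scans of an array, and compared 2 arrays with 2. All arrays were on 1 slide. Scans 1 and 2 of each group belonged to 1 scan session and scan 3 of each group to another; the second session holds 1 scan per group, so no test within it was possible.

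Spots of control probes and spots with a uniformity or population outlier mark were left out. The log2 signals of a probe's spots were averaged, and the 75th percentile over non-control probes of the array was subtracted. Probes well above background on at least 3 of the 6 scans were kept, 13225 in all; 5 of these had no fit, which left 13220. limma 3.58.1 (lmFit and eBayes, R 4.3.3) compared AP with control with 2 residual degrees of freedom, two-sided, and p values were adjusted by Benjamini and Hochberg over all probes tested; a probe changed at an adjusted p below 0.05. Where a probe was not well above background on any scan of a group, the fold is written as a bound. It was taken against the lowest signal of any probe well above background on the scan, or the probe's own signal where higher. That level is not the detection limit of each probe, so the bound is approximate. Where marked spots left a group with a value on 1 array, the fit took its spread from the other group; this held for 71 of the probes tested, 32 of them changed, and for 3 named genes (Dcn, Mt2A and Sparc). Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

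Of 24663 probes on the array, 15304 carried RefSeq coding accessions and counted as coding, 7096 carried noncoding identifiers, 2242 carried other GenBank or transcript identifiers and 21 could not be classed. Symbols came from a table of current rat RefSeq genes, matched on the accession without its version: 14256 coding and 20 noncoding probes were named, and 10387 probes kept only their identifier. Genomic positions were not used here, because the array design and the gene table belong to different assemblies. Where a gene had several probes, the brightest was used, which gave 8732 genes; for Add2, Bcl2l1, Cxcl12 and Pom121l2 another probe went the other way past the threshold.

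Fixed before the data were examined were 30 gene lists, the comparison, the rule for named genes and 21 of the 28 alternatives. The rule named the 10 coding genes with the largest change up and the 10 with the largest change down, the 5 noncoding RNAs each way, up to 4 members of each list, and 21 genes whatever their result. Members that are named to spell out a count of 5 or fewer were chosen after their values were seen. The values of some genes that the rule names are not reported here. Lists with at least 5 measured genes, 29 of the 30, were tested with camera (preset correlation 0.01) against all other genes. Camera with an estimated correlation and fry stand beside it. These list tests left out any gene without a value on every array of the setting, while the counts and medians of a list kept it. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so a call can be lost without a higher correlation. For the mitochondrial list the estimated correlation was 4.05e-05, and the unadjusted camera p went from 7.14e-06 to 0.0375. Counts adjusted over the list alone correct for the members of that list only.

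The procedure was tested on simulated data with the group sizes of these arrays. Spreads were drawn from the variance model of the fit, and each probe was drawn independently of the others. In 10 runs with 200 changed probes among 13149, a log2 change of 2 was recovered in 49.2% of probes and one of -2 in 50.6%, a change of 1 in 0.8% and one of -1 in 0.4%, and 6.13% of all calls were false. The list test found 100% of 4 shifted lists per run and called 1.2% of the 25 others. In the real comparison far more probes were called (7282 of 13220), and the adjustment depends on that share. The shares of recovered probes therefore do not carry over to it. Since probes were drawn independently, the list result does not bear on lists whose genes are correlated.

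The alternatives were quantile normalization, a shift by the median of probes above background on all scans, normexp background correction (offset 50) with either scaling, the deposited normalized values, no filter and a stricter filter on dim probes, a 2-fold threshold, averaged probes, a variance model with trend, array weights, the scan session or the replicate number as a block, leaving out each scan, and both other list tests. Normexp used median spot intensities, since the files held no mean. A filter on saturated probes was planned too and removed none. Chosen after seeing the data were 6 scans as separate replicates, the first scans alone, no scaling between arrays, a crossed pairing, leaving out the second array of either group with both its scans, and another class of noncoding probes. No sample was left out of the main comparison.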

Results

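The series held 6 deposited scans of 1-colour Agilent arrays that carried probes for messenger RNAs and long noncoding RNAs of the rat. Per the labels, 3 scans came from pancreas of control rats and 3 from pancreas of rats with acute pancreatitis (AP), an inflammation of the gland that was induced by injecting the bile salt sodium taurocholate backwards into the pancreatic duct. The labels give a 4% solution at 1 mL/kg, male rats of 6 weeks, and tissue taken 9 h after the injection; they do not say whether the control rats had a sham operation. The scans labelled control 2 and control 3 were 2 scans of 1 array, and so were AP 2 and AP 3. Deviations of single spots from the mean of their probe, which different arrays share in part, correlated across 2013 spots with r = 0.997 for the control pair and r = 0.994 for the AP pair, against 0.411 to 0.801 for the other 13 pairs (r across spots, which are not independent replicates). The file headers also gave both scans of a pair the same place on the slide, slot 2 for control 2 and 3 and slot 4 for AP 2 and 3. Control 1 was in slot 1 and AP 1 in slot 3, so an effect of the place on the slide cannot be told apart from the group. All tests therefore used 4 arrays, n = 2 per group, except for 71 probes with a value on 1 array of a group. The number of arrays limits the precision of every value.

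**Figure D1:**
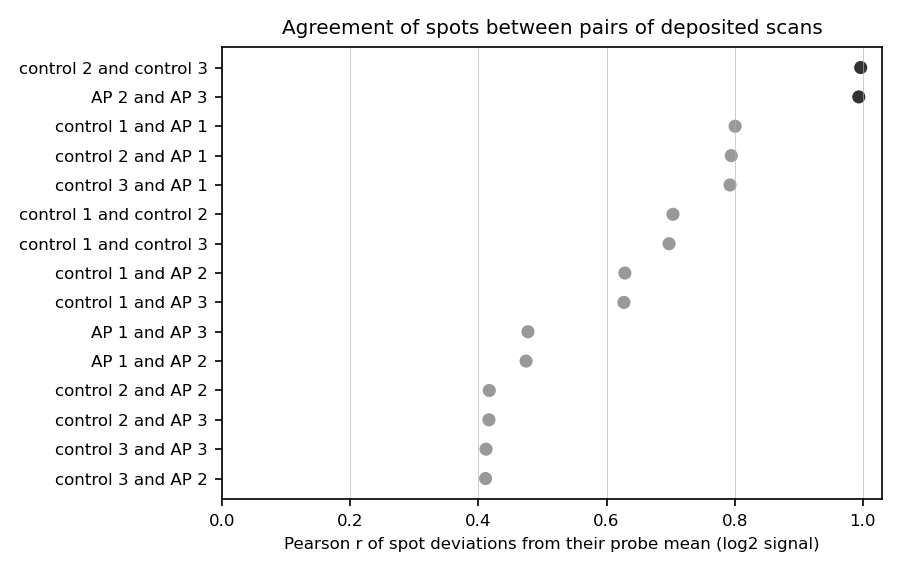
Each point is 1 of the 15 pairs of deposited scans, and the horizontal axis gives Pearson's r between the deviations of 2013 spots from the mean of their probe (log2 signal). The pair control 2 and control 3 and the pair AP 2 and AP 3 sit at 0.997 and 0.994, and the other 13 pairs lie between 0.411 and 0.801.

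The scans of the control group were brighter. The 75th percentile of the signal was 147, 140 and 146 on control 1, 2 and 3 and 77.7, 70.1 and 73.9 on AP 1, 2 and 3. Probes well above background numbered 15388, 13451 and 13039 on the control scans and 10905, 11367 and 10931 on the AP scans. No spot was saturated. Values are log2 signals relative to the 75th percentile of their array, which removed a mean difference of -0.96 (AP minus control). Without that scaling the median log2 fold change over 8732 genes was -0.99 instead of -0.03, so each fold below is relative to the signal of the whole array. This difference was not uniform: its median without scaling was -0.88 over the tested probes but -0.05 over the 250 brightest, so the same shift on every probe raised bright probes on the AP arrays. The shift raised probes at background there as well. Cd79b, at background on control arrays, stood at -5.37 on them, and Cxcl2, at background on AP arrays, at -4.25 on those. With no filter on dim probes 66.9% of the changed probes were higher on the AP arrays, against 48.8% with the filter. A rise of less than 0.96 in log2 has the opposite sign without scaling. Counts of list members adjusted over the list alone equal those adjusted over all probes unless both are given. Folds carry the SE of the limma fit and an adjusted p over 13220 probes.

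The comparison of AP with control asks which messenger RNAs and long noncoding RNAs of the pancreas changed in acute pancreatitis. Genes of inflammation and tissue injury were lower, not higher, on the arrays labelled AP. Cxcl2, which encodes a chemokine that attracts neutrophils, had a log2 signal of 5.24 ± 0.03 (SD, n = 2) on control arrays and was at background on AP arrays, at least 215-fold lower. Ccl2, a chemokine for monocytes, was 57.8-fold lower (log2 fold change -5.85 ± 0.09, SE, n = 2 per group, adjusted p = 0.000602), and Il6 and the GTPase Rnd1 were at least 29.1-fold and 28.8-fold lower. Il1b, the gene of interleukin 1 beta, was 15.8-fold lower (-3.98 ± 0.12, adjusted p = 0.00067). The direction follows the deposited labels, and the deposited normalized values gave the same direction. Over 153 genes of 8 injury lists, picked after the result was seen and named further below, the median log2 fold change was -1.32 here and -1.41 from those values.

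Of the cytokines and chemokines, 15 of 24 measured genes were lower, 3 were higher (Il10 1.88, Ccl20 1.59 and Tnf 0.49) and 6 were not past the threshold. The list fell against all other genes (median log2 fold change -1.54, or -1.39 with dim genes at their bound; adjusted p = 0.00441; adjusted p = 0.274 with an estimated correlation). Ccl7 was 62.6-fold lower and Cxcl1 14.2-fold lower. Tnf, unlike Il6 and Il1b, was higher (0.49 ± 0.10, adjusted p = 0.0231) and changed its call in 11 other settings. It was -0.47 without scaling (adjusted p = 0.0401). It lost its call under quantile normalization (adjusted p = 0.0821), with the deposited normalized values (0.0822), under both normexp settings (0.334 and 0.328), with a robust variance trend (0.0750), with the replicate number as a block (0.0691) and with any 1 array left out (0.0665 to 0.0990). Of the immediate early and AP-1 genes, transcription factors and phosphatases that respond within minutes to stress, 15 of 24 were lower, 2 were higher (Klf2 1.38 and Ier5 0.94) and 7 were not past it, or 17 lower and 2 higher adjusted over the list alone (median -1.24, or -1.09 with dim genes at their bound; adjusted p = 0.000571; adjusted p = 0.274 with an estimated correlation). Fosl1 was at least 9.88-fold lower, Atf3 at least 9.66-fold, and Dusp1 12.5-fold. Of the NF-kappaB target genes, 6 of 15 were lower, 1 was higher (Irf1 0.70) and 8 were not past it; Sod2, a mitochondrial superoxide dismutase, was 9.30-fold lower, and the list itself did not pass (median -0.39, or -0.25 with dim genes at their bound; adjusted p = 0.108).

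Genes of tissue repair followed the same direction. Of the matrix remodelling and fibrinolysis genes, 15 of 20 were lower, 2 were higher (Adamts5 2.27 and Plau 1.04) and 3 were not past the threshold (median -3.05, or -2.38 with dim genes at their bound; adjusted p = 0.000527; adjusted p = 0.274 with an estimated correlation). The proteases Adamts9 and Adamts1 were at least 24.5-fold and at least 19.3-fold lower. Of the pancreatitis-associated and acute phase genes, 13 of 24 were lower, 5 were higher (A2m 1.75, Saa4 0.77, Reg1a 0.62, Clu 0.55 and Reg3a 0.42) and 6 were not past it (median -1.25, or -1.14 with dim genes at their bound; adjusted p = 0.0365; adjusted p = 0.318 with an estimated correlation). Ptx3, a secreted pattern recognition protein, was at least 119-fold lower, Timp1, an inhibitor of metalloproteinases, 53.3-fold lower and Lcn2 14.3-fold lower. Reg3b, the pancreatitis-associated protein, had a log2 signal of 3.76 on control and 3.60 on AP arrays (-0.16 ± 0.09, adjusted p = 0.228). It was called lower without scaling (-1.12, adjusted p = 0.00203) and with 6 scans as separate replicates (-0.14, 0.0439). The acute phase list lost its call without AP replicate 1 (median -1.16, adjusted p = 0.0579), with probes above background on all scans (-0.16, 0.106) and without scaling (-2.21, 0.0538). The matrix list lost its call with probes above background on all scans (-1.63, 0.0515).

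Of the oxidative stress and metallothionein genes, 12 of 18 were lower, 1 was higher (Gclc 0.72) and 5 were not past the threshold, or 13 lower and 1 higher adjusted over the list alone (median -1.69, adjusted p = 0.00317; adjusted p = 0.318 with an estimated correlation). The metal-binding Mt1 was 17.1-fold lower, and Hmox1, the haem-degrading enzyme, 14.6-fold lower (-3.86 ± 0.14, adjusted p = 0.000755). Of the heat shock proteins, 10 of 16 were lower and 6 were not past it (median -0.99, adjusted p = 0.0126, and 0.325 with an estimated correlation). Without scaling the median of the heat shock list fell further (-1.95), but its call was lost (camera adjusted p = 0.0538). Hspb8 was 5.61-fold lower and Hsp90aa1 3.81-fold lower. Of the ER chaperones and folding factors, 8 of 18 were lower, 1 was higher (Syvn1 0.62) and 9 were not past it; Hspa5, the main chaperone of the endoplasmic reticulum, was 4.40-fold lower (-2.14 ± 0.13, adjusted p = 0.00162). The list did not pass (median -0.33, adjusted p = 0.233). Of the ATF4 and CHOP target genes, 10 of 20 were lower, 5 were higher (Ddit4 1.79, Slc7a11 1.19, Mthfd2 1.06, Shmt2 0.98 and Vldlr 0.97) and 5 were not past it. Ddit3, which encodes CHOP, was 4.66-fold lower and Cebpb 17.6-fold lower. The list as a whole did not pass (median -0.74, or -0.56 with dim genes at their bound; adjusted p = 0.181).

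Genes of T and B lymphocytes were higher on the arrays labelled AP. Ccl21, a chemokine that guides lymphocytes into lymphoid tissue, was 75.2-fold higher (6.23 ± 0.14, SE, n = 2 per group, adjusted p = 0.000602). Cd3e, a subunit of the T cell receptor complex, rose from -1.70 ± 0.02 to 2.92 ± 0.01 (SD, n = 2 per group), 24.7-fold, and the T cell kinase Lck was 33.9-fold higher (5.08 ± 0.31, adjusted p = 0.00164). Cd79b, a part of the B cell receptor, was at least 18.3-fold higher, Tnfrsf17, a receptor of plasma cells, at least 19.2-fold, and RT1-Bb, a class II histocompatibility chain, at least 231-fold. Art2b, Skap1 and Tnfrsf14, all expressed in lymphocytes, were at least 35.7-fold, 40.7-fold and 34.9-fold higher, and Dnase1l3, a secreted nuclease, was 54.3-fold higher. Of the lymphocyte and NK cell markers, 13 of 16 were higher, 1 was lower (Cd5 -0.48) and 2 were not past the threshold. The list rose against all other genes (median 3.39, or 3.22 with dim genes at their bound; adjusted p = 1.34e-05; adjusted p = 0.274 with an estimated correlation). Its median was 1.51 at the lowest under the other settings, and 12 of 16 genes lay above 0 without scaling.

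Markers of fat, blood and connective tissue were lower on the same arrays. Of the adipocyte markers, 11 of 15 were lower, 1 was higher (Pck1 1.04) and 3 were not past the threshold, or 12 lower and 1 higher adjusted over the list alone (median -3.72, adjusted p = 0.000527; adjusted p = 0.274 with an estimated correlation). Adipoq, the gene of adiponectin, fell from 5.85 to 0.92 (30.4-fold), and Fabp4, a fatty acid carrier, was 37.3-fold lower; the malic enzyme Me1, a source of NADPH, was at least 82.8-fold lower. Of the erythroid cell markers, 8 of 9 were lower and 1 was higher (Hemgn 1.22) (median -3.22, adjusted p = 0.00267, and 0.318 with an estimated correlation). Without scaling the erythroid median fell further (-4.18), but the call was lost (camera adjusted p = 0.0538). The beta globin gene Hbb was 24.8-fold lower (9.38 ± 0.15 on control arrays, 4.75 ± 0.02 on AP arrays, SD, n = 2 per group). Of the fibroblast and stellate cell markers, 9 of 12 were lower, 1 was higher (Fap 2.79) and 2 were not past it (median -1.77, adjusted p = 0.0314; adjusted p = 0.318 with an estimated correlation). Mgp, a matrix protein, was 6.33-fold lower. Sparc and Dcn in this list, and Mt2A among the oxidative stress genes above, had values on 1 control array only. The camera tests of these lists therefore left them out, while the counts and medians hold them. The median of the fibroblast list hardly moved but its camera call was lost without control replicate 2 (median -1.78, adjusted p = 0.0621). The same held with 6 scans as separate replicates (-1.76, 0.0626) and with the scan session as a block (-1.76, 0.0668). The genes that entered the camera test can differ between these settings, since missing values differ. Without scaling the call was lost too (-2.73, 0.262).

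Of the neutrophil markers, 9 of 12 were lower, 2 were higher (among them Ncf1 1.22) and 1 was not past the threshold (Cxcr2 0.24) (median -2.12, or -1.12 with dim genes at their bound; adjusted p = 0.0117; adjusted p = 0.286 with an estimated correlation). S100a8, a subunit of calprotectin, was at least 90.7-fold lower; Slpi, a protease inhibitor that epithelia also make, was 140-fold lower. Outside the list, Mcemp1 was at least 57.5-fold lower and Wfdc21 89.4-fold lower. The neutrophil list lost its call under normexp background correction with the 75th percentile shift (median -0.11, adjusted p = 0.0784), with probes above background on all scans (-1.65, 0.363, over 5 genes) and without scaling, where the median fell further (-3.07, 0.311). Of the monocyte and macrophage markers, 8 of 18 were lower, 3 were higher (Marco at least 9.13-fold, Plac8 1.37 and Csf1r 0.36) and 7 were not past it; Marco lost its call without AP replicate 1 (adjusted p = 0.0602) or the second AP array (0.0577). Ccr1 was 13.6-fold lower. As a list these did not pass (median -0.20, adjusted p = 0.355).

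Digestive enzyme genes of acinar cells, the main cell type of the pancreas, were moderately higher on the arrays labelled AP relative to the whole signal. The enzyme genes named below were not bright in either group. Amy2a3, Cpa1 and Prss2 stood at 1.02, 0.26 and 1.67 on control arrays and at 2.10, 1.06 and 3.49 on AP arrays. Hbb and Fabp4 stood at 9.38 and 7.65 on control arrays and at 4.75 and 2.43 on AP arrays. Whether acinar RNA made up most of the signal in either group was not tested. Of the acinar digestive enzymes and secreted proteins, 12 of 25 were higher, 2 were lower (Pla2g1b -0.42 and Pnliprp2 -0.42) and 11 were not past the threshold (median 0.56, adjusted p = 0.00403; adjusted p = 0.275 with an estimated correlation). Without scaling the median was -0.40 (adjusted p = 0.122), and under normexp with the 75th percentile shift the call was lost (0.155). The amylase gene Amy2a3 was 2.12-fold higher (1.09 ± 0.10, SE, n = 2 per group, adjusted p = 0.00333), with 0.13 without scaling (0.383) and 0.60 under that normexp setting (0.0960). Cpa1, a carboxypeptidase, was 1.74-fold higher (0.80 ± 0.13, adjusted p = 0.0129). It stood at -0.15 without scaling, and lost its call under that normexp setting (0.320) and without control replicate 1 (0.0639) or the second control array (0.0713). Prss2, a trypsinogen, was 3.53-fold higher (1.82 ± 0.45, adjusted p = 0.0346) and lost its call without scaling (0.182), with no filter on dim probes (0.0616) and without control replicate 1 (0.114) or the second control array (0.149). Of the acinar transcription factors and secretory machinery, 7 of 18 were higher, 5 were lower (Chrm3 -1.31, Xbp1 -1.30, Fkbp11 -0.83, Rab3d -0.71 and Slc39a5, at background on the AP arrays) and 6 were not past it; Bhlha15, a transcription factor of secretory cells, was 4.13-fold higher, and the list did not pass (median -0.02, or 0.0051 with dim genes at their bound; mean 0.18; adjusted p = 0.480). Chrm3 lost its call under that normexp setting (adjusted p = 0.720) and without control replicate 1 (0.0633) or the second control array (0.0791).

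Of the duct cell markers, 8 of 14 were lower, 1 was higher (the bicarbonate transporter Slc4a4 2.39) and 5 were not past the threshold; the keratins Krt8 and Krt19 were 7.95-fold and 2.03-fold lower. This list did not pass (median -1.44, or -1.01 with dim genes at their bound; adjusted p = 0.109). Of the islet endocrine markers, 3 of 9 were lower (among them the insulin genes Ins2 and Ins1), 2 were higher (Slc30a8 at least 6.19-fold and Scg3 0.72) and 4 were not past it. Ins2 was at least 3.65-fold lower (-0.42 and adjusted p = 0.278 under normexp with the 75th percentile shift), and Ins1 was 2.69-fold lower; the median of the islet list was 0.27 and its mean -0.20, its median was -0.69 without scaling, and the list did not pass (adjusted p = 0.923). Of the endothelial cell markers, 7 of 9 were lower and 2 were higher (Cldn5 1.51, with adjusted p = 0.0563 without scaling and 0.0599 under that normexp setting, and Flt1 0.66); Sox18 was at least 8.37-fold lower. The list did not pass (median -1.09, adjusted p = 0.0904). Of the intestinal epithelium markers, 2 of 6 were lower (Cdh17 at least 2.09-fold and Lgals4 2.17-fold) and 4 were not past it. Cdh17 stood at 0.057 under normexp with the 75th percentile shift, and Lgals4 lost its call there (adjusted p = 0.526), with no filter on dim probes (0.0547), with the replicate number as a block (0.0759), and without control replicate 1 (0.0916), AP replicate 1 (0.106) or the second AP array (0.0600). These genes as a list did not pass (median -0.34, adjusted p = 0.457).

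Genes of energy metabolism were lower on the arrays labelled AP. Of the mitochondrial respiratory chain genes, 22 of 26 were lower, 1 was higher (Ndufa4 at least 6.75-fold) and 3 were not past the threshold, or 23 lower and 1 higher adjusted over the list alone (median -0.96, adjusted p = 0.000104; adjusted p = 0.274 with an estimated correlation). Cox5a, a subunit of cytochrome oxidase, was 3.65-fold lower, and the ATP synthase subunit Atp5f1b 2.94-fold lower. Of the hypoxia and glycolysis genes, 14 of 21 were lower, 2 were higher (Pfkfb4 1.25 and Pfkp 0.60) and 5 were not past it (median -1.58, adjusted p = 0.00238; adjusted p = 0.274 with an estimated correlation). The glucose transporter Slc2a1 was 6.26-fold lower and lactate dehydrogenase Ldha 5.96-fold lower. Of the autophagy and lysosome genes, 11 of 21 were lower, 1 was higher (Tfeb 0.83) and 9 were not past it, or 13 lower and 2 higher adjusted over the list alone (median -0.50, adjusted p = 0.0125; adjusted p = 0.318 with an estimated correlation). The lysosomal proteases Ctsd and Ctsl were 8.87-fold and 3.57-fold lower.

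Cell cycle genes were higher on the arrays on which the lymphocyte markers were higher (median 3.39). Of the cell cycle genes, 12 of 16 were higher, 1 was lower and 3 were not past the threshold, or 13 higher and 1 lower adjusted over the list alone (median 1.49, adjusted p = 0.000571; adjusted p = 0.274 with an estimated correlation). Ccna2, a cyclin of S phase and mitosis, was 7.40-fold higher and the ribonucleotide reductase subunit Rrm2 6.49-fold higher; the member that was lower was Cdkn1a, an inhibitor of the cycle (10.3-fold). Of the cytosolic ribosomal protein genes, 7 of 22 were higher, none was lower and 15 were not past it (median 0.37, adjusted p = 0.00267; adjusted p = 0.343 with an estimated correlation). Rpl6 was 3.44-fold higher. The ribosomal call was lost under quantile normalization (median 0.0068, adjusted p = 0.566), with the deposited normalized values (0.522) and under both normexp settings, and the median was -0.59 without scaling.

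Of the interferon-stimulated genes, 10 of 21 were lower, 4 were higher (Psmb9 1.85, Usp18 0.86, Psmb8 0.83 and Mx2 0.58) and 7 were not past the threshold; Isg15 was at least 12.9-fold lower. As a list these did not pass (median -0.46, adjusted p = 0.230). Of the cell death genes, 6 of 16 were lower, 3 were higher (among them Pycard 1.96 and Casp1 0.58) and 7 were not past it; the list did not pass (median -0.47, or -0.11 with dim genes at their bound; adjusted p = 0.355), and its highest median under another setting was 0.09. Bcl2l1, an inhibitor of apoptosis, was 4.97-fold lower on its brightest probe, another probe of the gene went the other way, and the mean of its probes gave 0.15. Of the EGF receptor ligands and dedifferentiation genes, 5 of 14 were lower (Plaur at least 27.4-fold, Areg at least 1.32-fold, Hbegf at least 1.29-fold, Myc -1.18 and Hes1 -1.15), 4 were higher (Krt23 3.63, Btc 1.33, Cd24 1.31 and Clu 0.55) and 5 were not past it. Under normexp with the 75th percentile shift Areg stood at 0.19 and Hbegf at 0.18, and Hbegf lost its call without AP replicate 1 (adjusted p = 0.0711) or the second AP array (0.0764). That list did not pass (median -0.08, adjusted p = 0.991). Clu, Myc and Plaur also belong to other lists above.

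**Figure D2:**
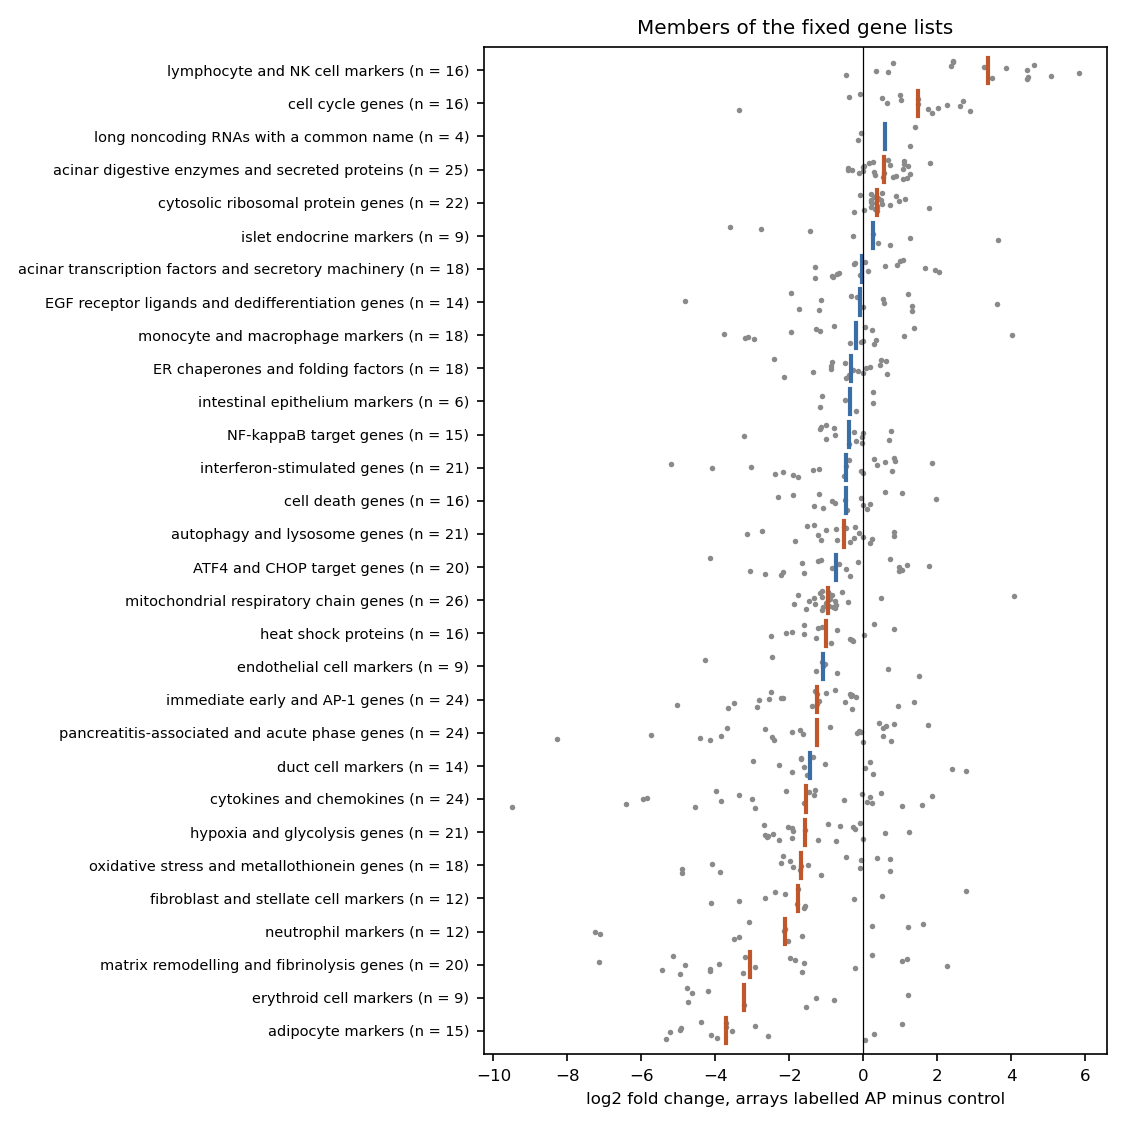
Each grey point is 1 measured gene of a list, the horizontal axis gives its log2 fold change (arrays labelled AP minus control, relative to the 75th percentile of the array), and the vertical bar is the median of the list, orange where camera passed at an adjusted p below 0.05 and blue where it did not or was not run. The lymphocyte median lies at 3.39 and the adipocyte median at -3.72; without scaling between arrays the acinar enzyme median turned from 0.56 to -0.40, the ribosomal median from 0.37 to -0.59 and the islet median from 0.27 to -0.69.

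**Figure D3:**
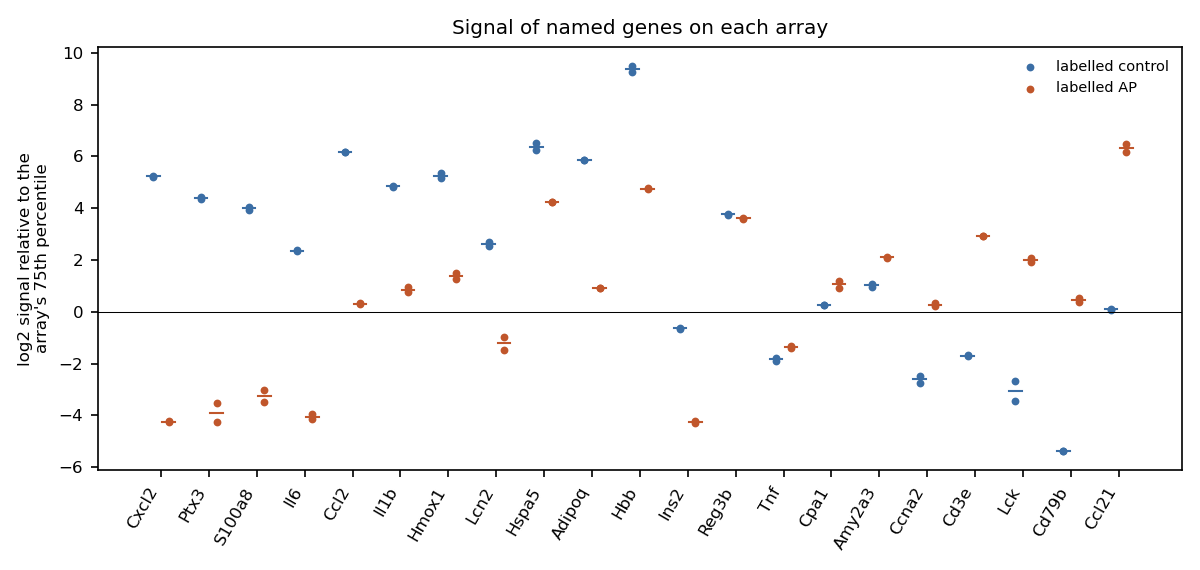
Points give the log2 signal relative to the 75th percentile of the array for named genes on each of the 4 arrays (n = 2 per group; the scans of 1 array averaged), and short lines give group means. Cxcl2 had means of 5.24 (control) and -4.25 (AP, at background), Cd3e -1.70 and 2.92, and Reg3b 3.76 and 3.60; Tnf and Cpa1 changed direction without scaling between arrays.

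Long noncoding RNAs changed in both directions, more of them upward. Of 2619 noncoding probes tested, 870 were higher and 494 were lower on the arrays labelled AP, so 63.8% of the 1364 changed probes were higher; 385 were higher and 286 lower by at least 2-fold. MRuc009bpr was 39.1-fold higher (5.29 ± 0.18, SE, n = 2 per group, adjusted p = 0.000719) and XR_008346 21.4-fold higher (4.42 ± 0.10, adjusted p = 0.000602). MRAK040987, MRuc008czd and MRAK086854 were at least 27.8-fold, 17.0-fold and 13.1-fold higher. MRAK132628 was 27.8-fold lower (-4.80 ± 0.09, adjusted p = 0.000602), and MRuc008sbh, MRAK159688, MRAK148690 and MRAK014000 were at least 41.7-fold, 14.8-fold, 11.4-fold and 7.54-fold lower. Of the ultraconserved elements, whose identifiers start with uc., 229 were tested, 80 were higher and 9 were lower. Without scaling between arrays 145 noncoding probes were higher and 1324 lower, so the split follows the scaling.

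Of the 40 long noncoding RNAs with a common name that were listed in advance, 4 were measured, too few for a list test; 2 were higher and 2 were not past the threshold (Gas5 -0.05 and Terc -0.15). H19, an imprinted noncoding RNA, was 2.66-fold higher (1.41 ± 0.11, SE, n = 2 per group, adjusted p = 0.00248) and lost its call under normexp with the 75th percentile shift (adjusted p = 0.0583). The probe listed as Rmrp was 2.39-fold higher (adjusted p = 0.00248; 0.0730 without scaling); the gene table used for names calls it Rpph1 but describes it as an RNase MRP RNA, so its identity is open between these RNAs. No probe could be named Malat1, Neat1, Meg3 or S100a9 here, and Ptf1a was below the filter.

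In all, 7282 of 13220 probes (55.1%) changed, 3557 higher and 3725 lower, and 3986 of them by at least 2-fold. Of 9532 coding probes, 2312 were higher and 2991 lower, 43.6% of the changed ones higher. The numbers up and down depend on the scaling: without it 768 probes were higher and 7796 lower (8.97% higher), and 506 coding probes were higher and 5940 lower (7.85%). Under normexp background correction with the 75th percentile shift 2659 probes changed, 35.2% of them higher, and of the coding probes 29.4%. With the second control array left out with both its scans, 4641 probes changed. The first scan session alone, with 2 arrays per group, gave 7233 changed probes; the second session held 1 scan per group. Of 29 gene lists tested, 17 passed, 4 up and 13 down, by camera in limma. With no filter on dim probes 23 passed, since the duct, endothelial, NF-kappaB, ER chaperone, ATF4 and interferon lists gained a call (adjusted p = 0.0287 to 0.0413), and the ER chaperone list gained one under normexp with the 75th percentile shift too (0.0103). The duct list also gained one without the second control array (0.0427). With an estimated correlation 0 passed, 1 had an unadjusted p below 0.05 (mitochondrial respiratory chain genes, p = 0.0375 from limma camera, before adjustment), and by fry, which tests a list's genes against no change, 28 passed. Normexp, which adds a constant to each signal, brought log2 changes closer to 0: at their closest, the medians of the adipocyte, matrix, cytokine and immediate early lists were -2.02, -1.25, -0.73 and -0.58.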

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

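Chosen after the result was seen were the settings without scaling, with 6 scans as separate replicates, with first scans alone, with an array left out, with a crossed pairing and with GenBank identifiers counted as noncoding. The counts of changed probes, coding probes and noncoding probes (7282, 5303 and 1364) stayed within 1.5 times except that they came to 2659, 2107 and 336 under normexp with the 75th percentile shift, to 4641, 3392 and 835 without the second control array, and to 3986, 2964 and 671 at 2-fold, which is a stricter rule; with no filter on dim probes 2873 noncoding probes changed, out of more tested. Leaving out each scan gave 5339 to 7300 probes, 3843 to 5313 coding probes, 1019 to 1375 noncoding probes and 16 to 17 lists; without replicate 1 of a group, or without its second array, the lone array was assumed to vary like the other group. With replicate number as a block 5516, 4048 and 1004 changed, and Tnf and Lgals4 lost their call. Deviations of the replicates correlated with r = -0.21 across probes, which are not independent replicates, and the crossed pairing gave 7292, 5293 and 1375. Of 29 lists, 17 passed, and 10 passed without scaling, 23 with no filter on dim probes, 0 with an estimated correlation and 28 with fry. Of 146 named genes, 112 kept their call under every setting that gave a value. In 9 the sign reversed (log2 fold change in brackets): under normexp with the 75th percentile shift Krt20 (0.040), Cdh17 (0.057), Areg (0.19), Hbegf (0.18) and Ifih1 (0.059), with probes averaged Bcl2l1 (0.15), and without scaling Tnf (-0.47), Cpa1 (-0.15) and Rpl4 (-0.065). Only Tnf was called in the other direction (limma adjusted p = 0.0401), and the others were not called there (0.314 to 0.925). Fry gave the EGF receptor ligand list (median -0.082) the opposite direction to camera. The cause of the other changes was not tested. Signal over background limits dim genes: the 5 that reversed under normexp had only a bound for their fold.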

Other observations

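The gene families and the tests of the injury genes and of scaling were chosen after the result was seen; the tests of lymph node genes, of noncoding signal and of other splits were written before. RT1 genes, which encode class I and class II histocompatibility molecules, were higher on the arrays labelled AP in 21 of 26 cases and lower in none (median log2 fold change 1.11, 0.15 without scaling). The class II chains RT1-Ba and RT1-Db1 stood at 2.83 and 3.88. Of 23 histone genes, 15 were higher and 5 lower (H2aj, H1f0, H2ab3, H3f3b and Hist1h2bq), with a median of 2.14 (1.07 to 2.17 under the other scalings), and H2bc12 stood at 4.14. Lymphocyte markers (median 3.39) and cell cycle genes (median 1.49) were higher on the same arrays.

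Of 19 aminoacyl-tRNA synthetase genes, which load amino acids onto transfer RNA, 13 were lower and 1 was higher (Qars1). Their median was -0.84, with -1.79 to -0.48 under the other scalings, and Yars1 stood at -1.67. Of 36 genes whose symbol marks a part of the proteasome, 25 were lower and 6 higher, with a median of -0.86 (-1.82 to -0.48 under the other scalings). Those that were higher included Psmb8, Psmb9 and Psmb10, the subunits of the immunoproteasome. Of 12 genes of fatty acid and triglyceride synthesis, 8 were lower and 1 was higher (Scd2), with a median of -3.91 (-4.87 to -2.23 under the other scalings). Adipocyte markers were lower on the same arrays, with a median of -3.72. No family was tested against other genes.

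The first pattern is that injury genes were lower on the arrays labelled AP. Of 8 injury lists, picked after the result was seen, 7 were called lower and none higher by camera. The 7 were the cytokine, immediate early, matrix, acute phase, oxidative stress, heat shock and neutrophil lists, and the NF-kappaB list did not pass. With an estimated correlation none of these calls held (camera adjusted p = 0.274 to 0.325). The related ER chaperone, ATF4, interferon, cell death and macrophage lists, outside the 8, did not pass either (camera adjusted p = 0.181 to 0.355). Group labels exchanged between the groups is a candidate explanation. Reg3b (-0.16) and Reg1a (0.62) did not follow the injury genes (median -1.32). Without scaling Reg3b was called lower (-1.12), and Reg1a, below the shift of 0.96, had a negative value. All genes moved then: the median was -2.27 over the injury genes and -0.99 over all genes, so both Reg genes stayed above the injury median. No value here excludes a true difference of the tissue pieces. A smaller share of acinar tissue on the arrays labelled control would lower every other cell type's markers on the arrays labelled AP. The lymphocyte median of 3.39 against an adipocyte median of -3.72 goes against 1 common dilution of all other cell types. This does not decide for the injury genes: the criterion was written after both medians were seen. Lymph node tissue, which stays open below, could also raise the lymphocyte genes by itself. Scaling between arrays is argued against, since the median over 153 genes nearest to 0 under any scaling was -0.65. The effect of pancreatitis itself, the difference the design names, stays open, as do the labels and the share of acinar tissue.

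The second pattern is that lymphoid genes were higher on those arrays. Lymph node tissue in the pieces labelled AP could bring them: of 9 lymph node marker genes not looked at before, 3 were higher (Fcer2 3.25, Mfge8 2.34 and Cxcl13 2.20) and 3 were lower (Pdpn -4.37, Bst1 -0.54 and Enpp2 -0.33), while the 3 seen before, Ccl21, Glycam1 and Ccl19, were higher by 6.23, 4.64 and 4.19. This share lies between the bounds set in advance, and lymph node tissue and a change in the gland cannot be told apart, since all 9 genes were above background in the control scans as well. Scaling between arrays is argued against, because the median nearest to 0 was 1.51 and 11 to 13 of 16 genes were called higher under every scaling. The criterion for that test was changed after its outcome was seen: the first one asked for a 95% interval above 50% of genes over 0, and without scaling 12 of 16 genes gave 47.6 to 92.7%, which did not decide.

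The third pattern is that changed noncoding probes were more often higher (63.8%) than coding probes (43.6%). Noncoding probes were dimmer, with a median log2 signal of 5.84 against 6.70, but coding probes drawn to the same signal were higher in 45.5%, over 10 points below the noncoding ones, which argues against dim signal as the whole cause. The shares were 62.4% against 43.0% under quantile normalization and 9.87% against 7.85% without scaling, so the size of the gap depends on the scaling. The medians of log2 fold change differed as well, 0.32 for noncoding and -0.03 for coding probes, a gap that a shift of whole arrays leaves as it is. These medians were not matched on signal, so dim signal may bear on their gap. The classes also differed in spots per probe: 962 of 7096 noncoding probes on the array had a single spot, against 15264 of 15304 coding probes. Whether averaging over spots bears on the contrast was not tested. With no filter on dim probes 83.8% of the changed noncoding probes and 57.7% of the changed coding probes were higher. No biological explanation was tested.

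The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. With limma, 1 of the 3, the real one, gave 7282 changed probes, and the others gave at most 0 (13 and 82 at an unadjusted p below 0.05). In the other splits each pair held 1 control and 1 AP array, so the difference between the groups entered the spread. Few calls were therefore bound to result, and these splits are no measure of the calls without a group difference.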
